A study of Caenorhabditis elegans with 2 samples.

How the data were processed

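Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on adult Caenorhabditis elegans of the strain fem-2(b245), grown at 20 °C per the labels. The gene fem-2 encodes a protein phosphatase of the sex-determination pathway that is needed for male development and for sperm in hermaphrodites. The samples comprised 1 ChIP library and 1 library of input DNA. The antibody was a rabbit polyclonal raised against a fragment of 100 residues of SCC-1, the kleisin subunit of the mitotic cohesin complex. Per the labels' protocols, frozen worms were ground, fixed with 1% formaldehyde for 10 min and sonicated, and 5 µg of antibody was used for the ChIP and 10 ng of DNA for the input library. The labels give the stage as a young adult with a germline, whereas the growth protocol describes gravid adults. The antibody is called affinity purified in the protocol and crude in its own record.

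Per the submitters' processing notes, reads were handled with BWA and the build was ce10, with no version of BWA given in the sources used here. Peaks were called with MACS on the build WormBase WS220, per the file headers and the peak records. The MACS version, its threshold and the use of the input library are not given in the sources used here. The deposited list gives for each peak a start, an end and a score, and the score is the authors' own value from their peak caller. The scale of the score is not named. The lowest deposited score was 50.08 and 1182 peaks had a score of exactly 3100, with 57 peaks above it, so scores did not resolve the upper end of the list, and 3100 may stand for scores too large to compute. Such scores grow with sequencing depth and with peak width, and were used here only within the list, to describe, rank, filter and group peaks and to compare those on X with those on the autosomes. Read counts per library were not analysed here, so the depth is unknown, and the signal of the input library was not analysed here as a background. There was no replicate.

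The start and end positions are 1-based, as deposited. All positions are on WS220. Gene annotation of that build was not used here, and positions were not converted to another build, so peaks were not assigned to genes. The planned comparisons of peaks with gene starts, gene lists and non-coding RNA genes were therefore not run. 1 further file of the series, with 1 score column, was not used, because its name and its peak names give another target and another antibody than the samples have.

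Chromosomes were described by the span from the first to the last peak, because chromosome lengths of WS220 were not used here. Peak density was the number of peaks per Mb of span, and covered length was the summed width of the peaks. The arms were the outer 25% of the span at each end and the centre was the middle part between them, with each peak placed by its midpoint. Density ratios carry exact (Clopper-Pearson) binomial 95% intervals, which cover counting error only and treat peaks as independent. Because peaks cluster, a second 95% interval was made by resampling blocks of about 1 Mb 10000 times. Differences of medians between X and the autosomes were tested with two-sided permutation tests of 100000 reassignments, with Benjamini-Hochberg adjustment over the 6 comparisons of scores and over the 4 comparisons of widths. Peaks are not replicates, so these tests describe this list and not a difference between conditions. The difference in arm to centre ratio between X and the autosomes was tested by permuting 1 Mb blocks, scaled to the mean of their own class, between X and the autosomes within arms and within centres. Blocks of a chromosome were treated as independent in both block methods and are not replicates either. Neither method accounts for dependence between neighbouring blocks. Spacing between neighbouring midpoints was set against 10000 random placements of the same peaks within each span, and adjusted over 21 comparisons. Further placements forbade overlap or kept each peak in its own 100 kb window, with 1000 placements where both held. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.

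The functions were tested on simulated peak lists. For the density ratios, peaks were placed uniformly and independently. With a true density ratio of 0.4 between X and the autosomes, the exact binomial 95% interval held the true value in 95 of 100 lists. For the arm to centre ratio with a true value of 1, it did so in 98 of 100 lists. These lists had no clustering, so they do not show how well the intervals cover in the real list. The block intervals and the permutation of blocks were not tested in this way. The spacing test passed 4 of 50 uniform lists and 50 of 50 lists with close pairs added. With placements that forbid overlap, 2 of 50 lists placed in that way passed. These spacing lists had peaks of equal width, unlike the real list, and were judged by the share within 2 kb. The test of the median distance was not checked in this way. The score test, run on the real numbers of peaks, passed 4 of 100 lists with equal scores and 94 of 100 lists in which scores on X were multiplied by 0.6.

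The peaks named in the text were the 10 with the highest score and the highest-scoring peak of each chromosome, with ties broken by position. This rule, the comparisons of density, score, arms and spacing, and most alternatives were fixed before the data were examined. The alternatives fixed beforehand were the top 50% and the top 25% of peaks by score, merging of peaks with gaps of 500 bp or less, other bounds of the arms, other distances between neighbours, covered length in place of peak number, and leaving out each chromosome. The block intervals, the permutation test of blocks, the comparisons of peak width between X and the autosomes, the comparisons by score class, the other placements and the separate treatment of the left end of X were chosen after seeing the data.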

Results

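SCC-1 binding was mapped in adult fem-2(b245) hermaphrodites in 1 ChIP library, with 1 input library sequenced beside it. SCC-1 is the kleisin that closes the cohesin ring in mitotically dividing cells. The results describe the authors' list of peaks from the ChIP library. The list held 6780 peaks, all on the 6 nuclear chromosomes, and no neighbouring peaks overlapped. They covered 11.9 Mb, or 11.9% of the 100.1 Mb between the first and last peaks of the chromosomes. The median width was 1219.5 bp, with quartiles of 862 and 2001 bp and a range from 362 to 16522 bp. The median score was 493, with quartiles of 148 and 2038. With 1 library and no read counts, the spread between samples and the depth behind each peak are unknown.

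The 10 peaks with the highest deposited scores lay on chromosomes I to IV. The scale of the score is not named, and 1182 peaks share the value 3100. If that value stands for scores too large to compute, those peaks would rank above the 57 with higher printed scores, so the order at the top of the list is uncertain. The peak with the highest printed score, 3228, lay on chromosome IV from 5085018 to 5087873. It was followed by peaks on chromosome I from 3732282 to 3735064 with a score of 3224, from 6626248 to 6627362 with a score of 3221, and from 10719868 to 10720767 with a score of 3219. The highest-scoring peak of chromosome III, from 12382398 to 12383498, also had a score of 3219. On chromosome II the peak from 7758202 to 7759332 had a score of 3216, the peak from 14398431 to 14401322 a score of 3209, and the peak from 8061945 to 8063245 a score of 3207. The list of the 10 highest was completed by peaks on chromosome I from 7857154 to 7859170, with a score of 3206, and from 5741403 to 5744772, with a score of 3206. These 10 peaks were between 900 and 3370 bp wide. The highest printed score on chromosome V was 3188, from 5274679 to 5276530. On X the highest printed score was 3100, shared by 60 peaks, the first of which lay from 58836 to 61508. For the same reason this value does not rank the X peaks below those of the autosomes.

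The X chromosome, which is dosage-compensated in hermaphrodites, carried fewer SCC-1 peaks than any autosome. X held 508 peaks, or 28.7 per Mb, and the 5 autosomes together held 6272, or 76.1 per Mb. The density on X was 0.377 of that on the autosomes, with an exact binomial 95% interval from 0.343 to 0.412 and an interval from 0.298 to 0.477 when blocks of about 1 Mb were resampled. X spanned 17.7% of the mapped length and held 7.49% of the peaks, with an exact binomial 95% interval from 6.88% to 8.15%. Chromosome III had the highest density, 101.2 peaks per Mb, followed by chromosome I with 97.8, chromosome II with 73.6, chromosome IV with 68.4 and chromosome V with 52.3. Against the single autosomes, the density ratio of X ran from 0.283 against chromosome III to 0.549 against chromosome V. The interval for the comparison with chromosome V ran from 0.493 to 0.610, so X lay below each autosome by more than the counting error.

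**Figure D1:**
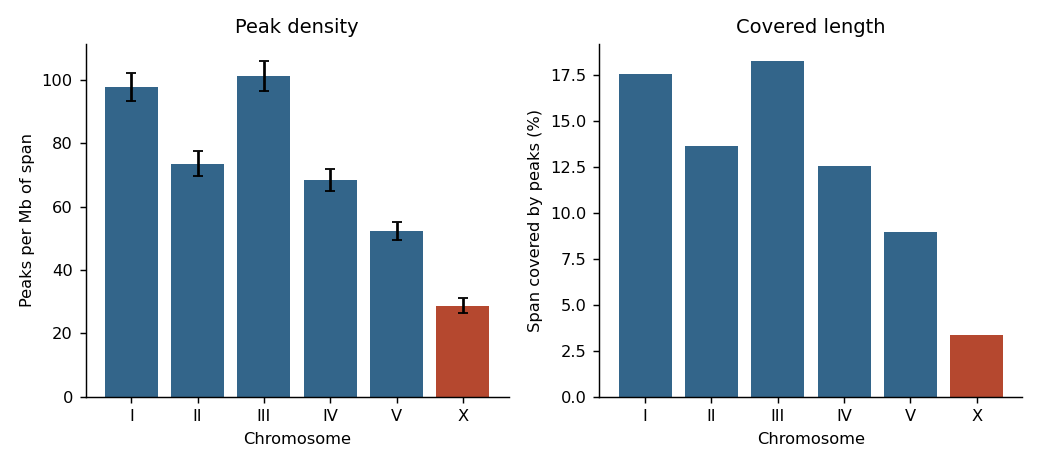
Peaks per Mb of span (left) and the percentage of the span covered by peaks (right) for each chromosome, with autosomes in blue and X in red. Error bars on the left are exact binomial 95% intervals of each chromosome's share of all peaks, for counting error only. X has 28.7 peaks per Mb and 3.37% of its span covered, the lowest values of the 6 chromosomes.

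In covered length the gap was wider. Peaks covered 3.37% of the span of X and 13.7% of the span of the autosomes, a ratio of 0.246. Among the autosomes the covered share ran from 8.93% on chromosome V to 18.3% on chromosome III. The median width of X peaks was 817 bp against 1254 bp on the autosomes, a difference of -437 bp (permutation p = 1e-05, the smallest that 100000 permutations can give). Broad peaks were also rarer on X. Of the 508 X peaks, 7 were 5 kb or wider, or 1.38% with an exact binomial 95% interval from 0.556% to 2.82%. On the autosomes 296 peaks were that wide, or 4.72% with an interval from 4.21% to 5.27%.

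X peaks also had lower scores. The median score was 274 on X and 533 on the autosomes, a difference of -259 (two-sided permutation test, p = 0.00036, adjusted p = 0.00036). Against each autosome alone the difference ran from -187 for chromosome V, with an adjusted p of 0.00013, to -296 for chromosome II, with an adjusted p of 4e-05. On X 60 peaks, or 11.8%, reached a score of 3100 or more, with an exact binomial 95% interval from 9.14% to 14.9%. On the autosomes 1179 peaks, or 18.8%, did so, with an interval from 17.8% to 19.8%. The difference of medians did not pass the test among the top 50% of peaks by score, where it was -323 (permutation p = 0.18).

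The density ratio between X and the autosomes was lower among peaks with higher scores. This trend restates the lower scores of X peaks in terms of density and is not separate support for them. All peaks were ranked by score and divided into 4 classes of 25% each. In the lowest class the ratio was 0.563, with an exact binomial 95% interval from 0.480 to 0.657. In the next classes it was 0.435, then 0.279, and in the highest class 0.243, with an interval from 0.192 to 0.302. The intervals of the lowest and the highest class did not overlap. X peaks were narrower than autosomal peaks in all 4 classes. The difference of median width was -77 bp in the lowest class (718 against 795 bp) and -1036.5 bp in the highest (1630.5 against 2667 bp). The permutation test passed in each class, with adjusted p-values between 1.3e-05 and 6e-05.

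**Figure D2:**
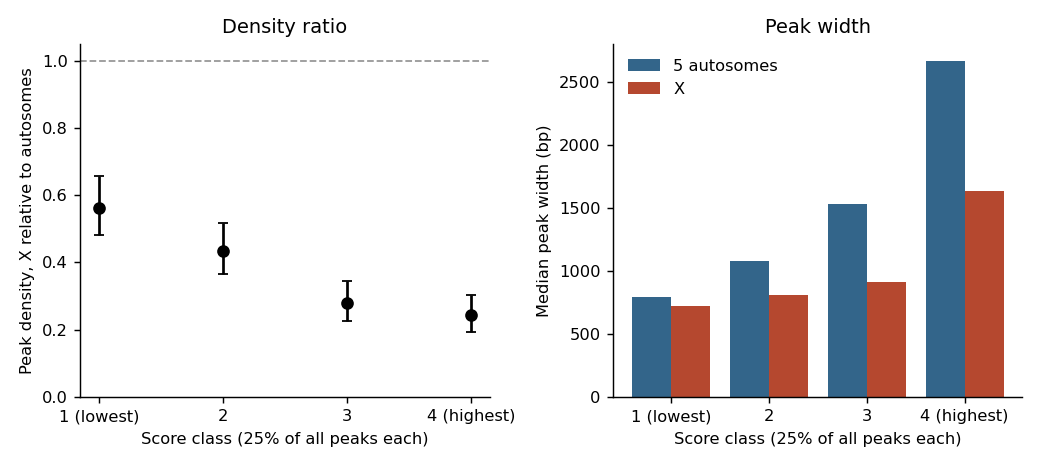
Left, peak density on X relative to the 5 autosomes within each of 4 score classes, each with 25% of all peaks, with exact binomial 95% intervals. Right, median peak width in bp on the autosomes (blue) and X (red) in the same classes. The density ratio is 0.563 in the lowest class and 0.243 in the highest, and X peaks are narrower in each class.

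On the autosomes, SCC-1 peaks were denser in the chromosome centres than in the arms. The arms of C. elegans autosomes are rich in repeats and the centres are rich in genes. The 5 autosomes together had 67.2 peaks per Mb in the arms and 85.1 in the centres, a ratio of 0.790 with an exact binomial 95% interval from 0.751 to 0.831 and a block interval from 0.689 to 0.910. Each autosome had a ratio below 1, from 0.662 on chromosome V to 0.880 on chromosome IV. For chromosomes II and IV the block intervals reached 1.02, so at that scale their difference was not larger than the spread between blocks. Peaks covered 10.6% of the arms and 16.7% of the centres of the autosomes, and the median score was 470 in the arms and 598 in the centres.

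X showed the opposite order. It had 35.0 peaks per Mb in the arms and 22.4 in the centre, a ratio of 1.57 with an exact binomial 95% interval from 1.31 to 1.88. With blocks of about 1 Mb, assigned to arm or centre by their middle, the ratio of X was 1.47. Its block interval was wider, from 1.00 to 2.09. The same blocks gave 0.794 on the autosomes. These block ratios differed by 0.88 on the log2 scale (permutation test of 18 X blocks and 82 autosomal blocks, p = 0.0011). That test treats the blocks of a chromosome as independent, and all X blocks come from 1 chromosome. The left end of X was its densest part. The first 1.5 Mb of X, a window chosen after seeing the data, held 118 of the 508 peaks on 8.47% of the span, or 78.7 peaks per Mb against 24.1 on the rest of X. Without this window the arm to centre ratio of X was 1.17, with an interval from 0.952 to 1.43. The left arm had 1.86 times the density of the centre, with an interval from 1.51 to 2.28, and the right arm 1.27 times, with an interval from 1.01 to 1.60. Without the first 2 blocks of X the difference from the autosomes was 0.45 on the log2 scale and did not pass the permutation test (p = 0.078). These parts were taken out because they were dense and lie in an arm, so that their removal could only lower the ratio. When the 5 fullest 250 kb bins of the arms and the 5 fullest of the centre were both removed, the ratio of X was 1.33, with an interval from 1.07 to 1.65. Over all 6 chromosomes the arm to centre ratio was 0.831, with an exact binomial 95% interval from 0.792 to 0.872. The block interval was wider, from 0.704 to 0.990.

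**Figure D3:**
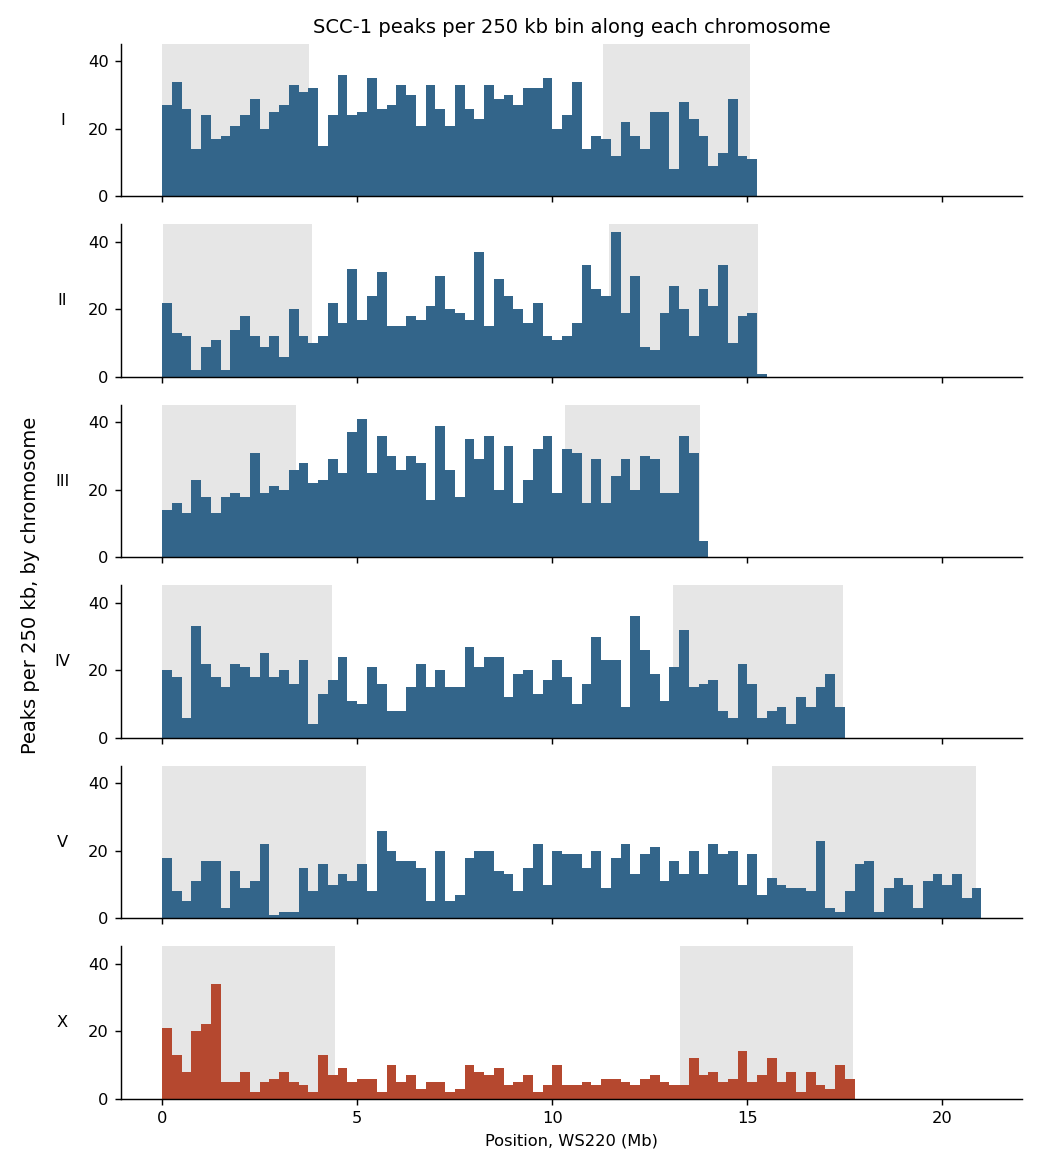
Number of SCC-1 peaks per 250 kb bin along each chromosome, in Mb on WS220, with autosomes in blue, X in red and the arms (the outer 25% of the span at each end) shaded in grey. The last bin of each chromosome is incomplete. On X the bin from 1.25 to 1.5 Mb holds 34 peaks, against a median of 6 peaks per bin on that chromosome.

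**Figure D4:**
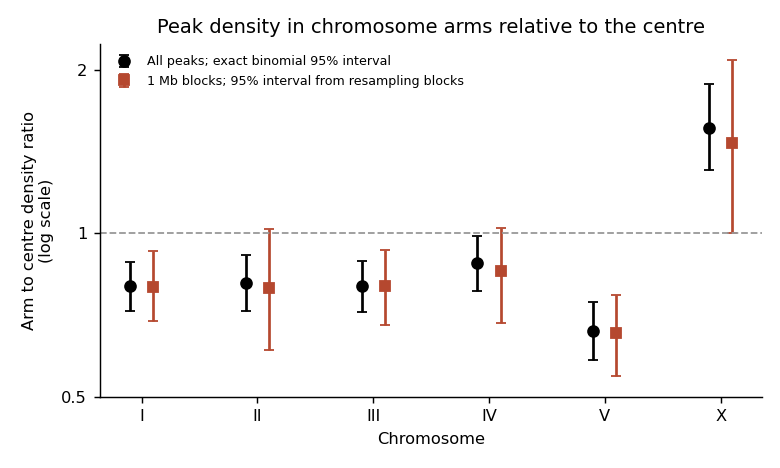
Peak density in the arms relative to the centre for each chromosome, on a log axis. Black circles use all peaks with exact binomial 95% intervals, and red squares use blocks of about 1 Mb with 95% intervals from resampling blocks. The 5 autosomes lie below 1 and X lies above 1, at 1.57 with all peaks and 1.47 with blocks.

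Neighbouring peaks lay closer together than peaks placed at random. The median distance between neighbouring midpoints was 5.70 kb, whereas it was 9.31 kb on average over 10000 uniform placements, 95% of which lay between 9.08 and 9.54 kb (two-sided permutation p = 0.0002, the smallest the placements can give, adjusted p = 0.00026). The observed median was below the placements on each of the 6 chromosomes. It ran from 4.71 kb on chromosome III to 17.7 kb on X, where the placements averaged 24.1 kb. Uniform placements ignore differences in density along a chromosome, such as the dense left end of X. Placements within 100 kb windows were made only over all chromosomes together. The share of neighbours within 5 kb was 46.4%, against 31.5% in the placements. At 2 kb the result depended on whether placed peaks could overlap, as called peaks cannot. Over all chromosomes 13.5% of the 6774 neighbouring pairs lay that close, against 14.2% in the uniform placements, which allow overlap (permutation p = 0.11, adjusted p = 0.12). Against placements that allow overlap, this pooled value joined opposite differences. Against those placements the share was lower on chromosome I, 13.7% against 17.8%, and on chromosome III, 14.9% against 18.3% (adjusted permutation p = 0.00026 for both). It was higher on chromosome V, 13.3% against 9.93% (adjusted permutation p = 0.0012), and on X, 8.48% against 5.56% (adjusted permutation p = 0.0065), and did not pass on chromosomes II and IV. With placements that forbid overlap the expected share over all chromosomes was 4.61%, with 95% of placements between 4.13% and 5.11%. The observed 13.5% lay above them (permutation p = 0.0002). Such placements were not run for single chromosomes. The lower shares on chromosomes I and III therefore do not show fewer close neighbours than random placement without overlap would give.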

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

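The ratio of peak density between X and the autosomes stayed below 1 under each alternative run. It was 0.261 in the top 50% and 0.243 in the top 25% of peaks by score, 0.429 after merging of peaks 500 bp or less apart, and 0.246 for covered length. It was 0.341 without chromosome V, 0.316 without the first 1.5 Mb of X, and 0.563, 0.435, 0.279 and 0.243 in the 4 score classes. Leaving out another autosome kept it within the counting error. The difference in median score was -323 in the top 50% and no longer passed, and it was 0 in the top 25%, where both medians lay at the value at which scores pile up. The peak number was 3390 and 1695 in those subsets by construction. There the median width was 1906 and 2609 bp, against 1219.5 bp in the full list. The covered share of the span was 8.38% and 5.42%, against 11.9%. The arm to centre ratio of all chromosomes was 0.765 in the top 50%, 0.747 in the top 25% and 0.790 without X. On X alone it was 1.17 without the first 1.5 Mb and 1.17 without the 5 fullest 250 kb bins, each with an interval that included 1, both removals being of dense parts of the arms alone. It was 1.33 without the 5 fullest bins of the arms and of the centre and 1.73 in the top 50%. It was 1.44 and 1.60 with wider and narrower arms and 1.55 after merging. The exact binomial intervals of these values lay above 1, but they cover counting error only. The share of neighbours within 2 kb, 13.5%, depended on the placements: it lay below those within 100 kb windows that allow overlap, 16.1%, and above those without overlap, 4.61%, also within windows, 5.63%. At 5 kb the share was 46.4%, above the placements. The shares of 0.930% at 1 kb, 3.07% in the top 50% and 3.12% after merging lay below the placements that allow overlap, 7.38%, 7.64% and 11.6%. They lay above those that forbid it, 0.253%, 0.931% and 1.28%. The median distance stayed below the placements in all 6 alternatives. The window at the left end of X, the score classes, the fullest bins and the placements in windows or without overlap were chosen after seeing the data. X could not be left out of a comparison that rests on it. No paired analysis was possible because the groups share only 1 replicate number and a peak list was analysed for the ChIP library alone. Without read counts, a lack of peaks cannot be told from a lack of depth.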

Other observations

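Peaks at the left end of X were as dense as on an autosome, in a window chosen after seeing the data because it was dense. Single autosomes ran from 52.3 peaks per Mb on chromosome V to 101.2 on chromosome III. The first 1.5 Mb of X had 78.7 peaks per Mb, against 76.1 on the 5 autosomes, but their median score of 275 and median width of 880.5 bp were close to those of X as a whole, 274 and 817 bp. The left and right arms also differed in density by more than the counting error on chromosomes I, II, III, IV and X. That error treats peaks as independent and does not cover their clustering. Chromosome I had 98.6 peaks per Mb in its left arm and 75.2 in its right, chromosome IV had 73.5 and 54.5, and X had 41.6 and 28.5. The order was the opposite on chromosome II, with 46.98 in the left arm and 84.8 in the right, and on chromosome III, with 75.5 and 104.3. On chromosome V the arms had 43.9 and 39.3 peaks per Mb, and the left share of arm peaks, 52.8%, had an exact binomial 95% interval from 47.9% to 57.5%.

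Of all peaks, 36 were 10 kb or wider, and 1 of them lay on X, from 16929142 to 16940096. The widest, 16522 bp, lay on chromosome II from 11964429 to 11980950 and had a score of 3100. The next, 16027 bp, lay on chromosome II from 11104971 to 11120997 with a score of 1388. The longest stretch without a peak was 404 kb, on chromosome V from 2800046 to 3204228, longer than the longest on X, 229 kb from 5518773 to 5747448. On chromosomes I, IV, V and X the first peak began at base 1, and on chromosome III at base 2. These peaks at the left ends had scores between 248 and 1185. No explanation was tested for these values.

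The tests of chromosome length, of fusion by covered length, of the score classes, of the fullest bins, and of placements in windows or without overlap, and the use of the median distance to weigh explanations, were chosen after the peak list had been examined. SCC-1 peaks were fewer and narrower on X. The values argue against 3 explanations of the number, each taken in a simple form and as the only cause. A line through the 5 autosomes, along which density fell with length, predicted 67.0 peaks per Mb for X, and X had 0.428 of that. When each autosome was predicted from a line through the other autosomes, the lowest ratio was 0.827, on chromosome II. These lines rest on few chromosomes, and the error of the prediction was not estimated. Fusion of neighbouring peaks would leave the covered length nearer to the autosomes, but its ratio of 0.246 lay below the ratio of peak numbers, 0.377. If all scores on X were lower by 1 common factor of up to 20, the lowest score class would be at least 0.784 as dense on X. The observed ratio was 0.563, with an upper bound of 0.657. Lower scores alone would leave no difference in width at equal score, and X peaks were narrower in 4 of 4 score classes. Scores were not equal within a class: they ran from 50.08 to 147.94 in the lowest and from 2042.56 to 3228.29 in the highest. The classes therefore cannot decide whether lower scores account for the narrower peaks. Lower signal on X in another form, or as part of the cause, was not tested and stays open. Mappability, a difference of input signal between chromosomes and a biological difference of X, such as its low transcription in the germline, were not tested and may each contribute.

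The reversed order of arms and centre on X was found in 1 of 6 chromosomes. It was not confined to low-scoring peaks, since the ratio was 1.73 among the top 50% of peaks by score, with an interval from 1.26 to 2.38. The intervals given here are exact binomial ones, which treat peaks as independent, and the block interval of all X peaks began at 1.00. Whether a few dense blocks account for it cannot be told from these values. Without the 5 fullest 250 kb bins of X, all in its arms and 4 of them in the first 1.5 Mb, the ratio was 1.17 with an interval from 0.956 to 1.43, but bins picked for fullness on one side could only lower it. Taking out the 5 fullest bins of the arms and the 5 fullest of the centre alike left 1.33, with an interval from 1.07 to 1.65, and no biological explanation was tested.

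Peaks lay close to their neighbours by the median distance of 5.70 kb and, where placed peaks could not overlap, by the share within 2 kb. Density that varies over 100 kb or more did not account for it alone. Placements that kept each peak in its own 100 kb window gave a median of 8.23 kb, with 95% of them between 8.03 and 8.43 kb. Without overlap, such placements gave a share within 2 kb of 5.63%, against 13.5% observed. Splitting of broad regions across gaps of 500 bp or less did not account for it alone, since after merging the median was 8.38 kb, below the 12.02 to 12.54 kb of placements with the same limit on gaps, and the share was 3.12%, above their 1.00% to 1.58%. Merged peaks were not placed within 100 kb windows, so splitting and regional density acting together were not tested. That combination, splitting across wider gaps and grouping of binding sites along genes remain open.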
